A study of Mus musculus with 2 samples.

How the data were processed

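Single-cell ATAC-seq measures open chromatin by letting the Tn5 transposase insert adapters into accessible DNA of single droplet-barcoded cells or nuclei. The series holds 2 mouse libraries, 1 per group, made with the 10x Genomics procedure. The ASCP tumor library came from an orthotopic transplant, grown in an NSG (immunodeficient) recipient, of a primary adenosquamous carcinoma of the pancreas (ASCP). The Pre-cancer library came from pancreas cells taken 5 weeks after tamoxifen was given at 8 weeks of age. Both carry Msi2-CreER, a tamoxifen-inducible Cre recombinase at the Msi2 locus, and MycT58A, a Myc allele whose protein is more stable.

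The deposited files are droplet barcodes and peak positions for each library, and for the Pre-cancer library also the raw counts per peak and barcode, which the authors deposited for every barcode and not only for called cells. The count matrix of the ASCP tumor was not analysed here, so nothing below gives a level of accessibility in the tumor: the libraries were compared by peak positions alone. The peak lists differ between the libraries and carry no score, height or p-value. Genome build mm10 and Signac 1.1.1 are named in the submitters' processing notes, with no role given. The aligner, the peak caller and the cell calling are not given in the sources used here. The deposited counts were whole numbers, and 90.9% of the nonzero values were even, as when both ends of a fragment are counted. Intervals on counts were therefore computed on fragments (counts divided by 2 and rounded up). They are 95% intervals for counting error only and say nothing of the spread between animals.

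Gene positions came from an NCBI table for GRCm38.p6, whose coordinates are those of mm10. The table gives a gene's start and end but no strand, transcription start site or exon. The promoter windows planned before the data were examined were therefore replaced by windows of 1 kb around either annotated end of a gene (gene-end peaks), and the planned gene body plus 2 kb upstream by the gene plus 2 kb on both sides (gene region). Whether a peak is exonic or intronic is not given for the same reason. The planned count of transcription factor motifs was not run, since no genome sequence was used here. Peak starts were read as 0-based and are printed 1-based. In the ASCP tumor list, 2 lines had been emptied for this work.

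Peaks counted as shared when they overlapped by at least 1 bp. For each of 21887 protein-coding genes the log2 ratio of the number of ASCP tumor peaks plus 1 to the number of Pre-cancer peaks plus 1 was taken over the gene region, minus the median of genes with a peak in either list. Peak number was the measure chosen before the data were examined, and the covered length with 500 bp added was a second measure, also chosen then. Since neighbouring peaks can be merged into 1 wide peak, both measures are given for each list. The median of a fixed gene list is given as its percentile among 10000 random lists of the same size, matched on 10 bins of the summed peak number or covered length. A percentile at or beyond 2.5 or 97.5 describes these 2 libraries and is not a p-value. Gene-end peaks were treated the same way, by the members with an ASCP tumor peak alone minus those with a Pre-cancer peak alone.

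Cells of the Pre-cancer library were barcodes with 1000 to 50000 counts. Peaks seen in at least 10 cells were binarised and weighted by term frequency and inverse document frequency, and components 2 to 30 of a singular value decomposition gave a graph of 15 nearest neighbours for Leiden clustering at resolution 0.5 (scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9). No doublet caller was run in the main clustering. Another run, also chosen before the data were examined, left out cells whose neighbours were mostly simulated doublets, which were 3 of 224 cells. The markers were fixed before the data were examined, but the rule that named the classes was not: a cluster was called ductal-like when its acinar list lay under 0.5-fold and its ductal list at 1.5-fold or more of the other cells, and the remaining clusters were called acinar-like. Counts over gene regions are given as CPM, counts in a region per 1000000 counts in peaks. A fold against 0 counts was ranked with a floor of 3 counts over the class and is given by the lower limit of its interval. Class-specific peaks had at least 20 counts in the class and a fold of at least 4. Their share in the ASCP tumor list was set beside 1000 draws of other peaks matched on width and total count. Shares have exact Clopper-Pearson intervals.

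Genes were named by a rule fixed before the data were examined. It took all members of the stem and progenitor list, up to 4 members per list with the largest centred ratio, the 10 highest and 10 lowest ratios among genes with at least 8 peaks, and per class 5 marker members, 5 leading genes with at least 50 counts, and 3 class-specific peaks on either side of the overlap with the ASCP tumor list. Some genes that the rule takes are not reported here. Other names are stated as chosen after their values were seen.

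The scripts were tested on simulated data. Overlaps were identical with those of bedtools 2.31.1. Of random lists with no shift, 5.5% fell outside the 2.5 to 97.5 percentile range, over 5000 simulated genes. Peaks raised 8-fold in a simulated class of Pre-cancer cells were called in 100% of cases, in a simulated matrix of 124391 peaks. The raised peaks were drawn from well-covered ones and called with the true class labels. The value therefore does not cover shallow peaks or classes found by clustering. The clustering put 100% of the changed cells in 1 cluster when 2000 peaks were raised 8-fold, and 76.7% when 200 were. It also split cells drawn from a single profile into 2 clusters, so the number of clusters is no evidence of that many kinds of cell. Analyses ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures in matplotlib 3.10.9. With 1 library per group, no test between the groups was possible and no p-value was made. Alternatives covered the overlap rule, peak and cell filters, window sizes, pseudocounts, clustering settings and class thresholds.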

Results

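Chromatin accessibility was profiled in single cells of the mouse pancreas at an early stage after activation of stabilised Myc in Msi2-expressing cells, and in a transplanted adenosquamous carcinoma of the same model. There was 1 library in each group, so no value has a replicate. The ASCP tumor list held 211232 peaks covering 201.9 Mb, with a median width of 575 bp. The Pre-cancer list held 124391 peaks covering 85.2 Mb, with a median width of 440 bp. The Pre-cancer matrix held 13585320 counts, and the depth behind the ASCP tumor peaks is unknown. Since the lists differ in length, gene ratios are given relative to the median gene. Its log2 ratio was 0.42 by peak number and 0.81 by covered length. Peak numbers and lengths given for single genes are not adjusted for this.

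Most accessible positions of the Pre-cancer pancreas were also peaks in the tumor. Of the Pre-cancer peaks, 86448 (69.5%, 95% interval 69.2 to 69.8) overlapped an ASCP tumor peak, and these held 94.4% of the counts. Conversely, 78579 ASCP tumor peaks (37.2%) overlapped a Pre-cancer peak, and 132653 did not. The share rose from 32.4% in the lowest of 10 bins of Pre-cancer peaks by count to 99.5% in the highest. Median peak width rose as well, from 36 bp to 1923 bp, so depth and width cannot be told apart here. Among protein-coding genes, 14528 (66.4%) had a gene-end peak in both lists, 2151 (9.83%) in the ASCP tumor alone and 306 (1.40%) in the Pre-cancer list alone. The last 2 counts were 1423 and 594 with the widest ASCP tumor peaks taken to equal number, and the Pre-cancer count was 98 with Pre-cancer peaks of at least 20 counts in barcodes of at least 5000 counts. All 20 housekeeping genes and all 16 proliferation genes had one in both. The overlap rule sets the shared value: with a reciprocal overlap of 50% it was 33.7%.

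Chromatin over squamous and basal epithelial genes covered far more sequence in the ASCP tumor list. The 20 genes of this list, which encode keratins, desmosomal and hemidesmosomal proteins and the transcription factor p63, carried 281.1 kb of ASCP tumor peaks and 57.8 kb of Pre-cancer peaks. By covered length the list median lay 1.63 log2 units above the median gene (percentile 100 of matched lists), with 18 of 20 members higher. Trp63, which encodes p63 (chromosome 16, 25683763 to 25892088), had 32 peaks covering 36.7 kb against 3 covering 0.15 kb. Dsg3, a desmosomal cadherin, had 7 against 0 peaks. Lama3, a laminin chain of the epidermal basement membrane, had 35 against 10. Krt17 had 1 peak that filled its whole gene region (8.82 kb) against 2 peaks covering 0.80 kb. Gene-end peaks were found in the ASCP tumor alone for 7 members and in the Pre-cancer list alone for 0 (percentile 99.6), an excess at percentile 99.5 or above with the other windows and peak filters tried. All 7, among them Krt14, Krt15, Krt6a, Pkp1 and Col17a1, were chosen after their values were seen, apart from Dsg3. The control list of 20 genes of other tissues had the same counts at gene ends, 7 and 0 (percentile 98.2). The excess at gene ends was therefore not particular to squamous and basal genes. By the planned measure, the number of peaks, the squamous or basal list did not stand apart: its median was 0.17 (percentile 72.5), and it was -0.053 with 10 kb on both sides of the genes.

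Acinar genes, which encode the digestive enzymes of the exocrine pancreas and their regulators, showed the opposite by covered length. The 18 genes carried 240.2 kb of Pre-cancer peaks and 47.7 kb of ASCP tumor peaks, a list median of -2.87 log2 units relative to the median gene (percentile 0), with 18 of 18 members lower. Nr5a2, a nuclear receptor of acinar cells (chromosome 1, 136842562 to 136960448), had 33 Pre-cancer and 10 ASCP tumor peaks. Zg16, a zymogen granule protein, had 1 Pre-cancer peak and none in the tumor. Cela1, an elastase, lay under 1 Pre-cancer peak of 15.8 kb, within which the ASCP tumor list had 5 peaks covering 6.23 kb. Cela2a had 2 peaks covering 14.1 kb in the Pre-cancer list and 7 covering 3.47 kb in the tumor. Gene-end peaks of 2 members, Pnlip (chosen after its values were seen) and Zg16, were in the Pre-cancer list alone (percentile 0.30). The balance was -4 with a window of 500 bp and -7 with the widest ASCP tumor peaks (percentile 0 for both), but 0 with 2500 bp (percentile 16.3). By the number of peaks the acinar list again did not stand apart, and its sign was turned: the median was 0.17 (percentile 84.5), with 10 members higher and 7 lower.

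**Figure D1:**
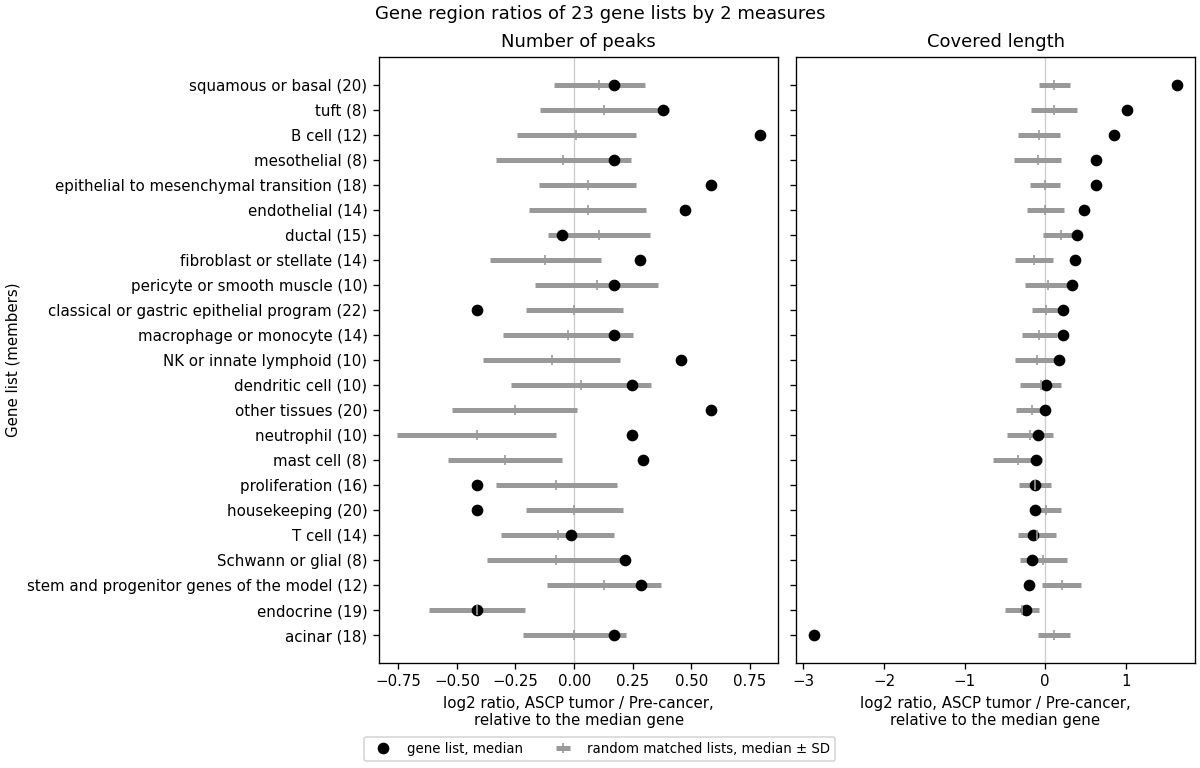
Median log2 ratio of ASCP tumor to Pre-cancer over the gene regions of 23 gene lists, relative to the median gene, by number of peaks (left) and by covered length (right). Black points are lists and grey bars the median ± SD of matched random lists; the acinar list lies at 0.17 by peak number and at -2.87 by covered length, the squamous or basal list at 0.17 and 1.63.

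**Figure D2:**
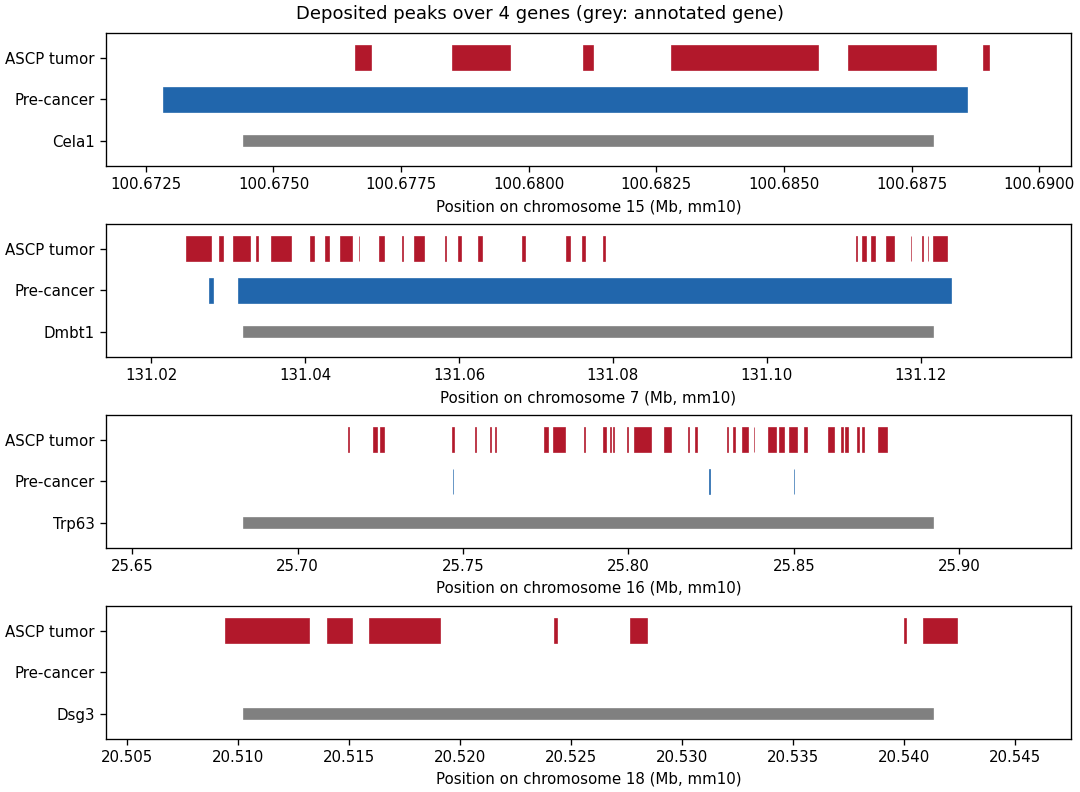
Deposited peaks of the ASCP tumor (red) and of the Pre-cancer library (blue) over 4 genes (grey), by position in Mb on mm10. Single Pre-cancer peaks lie over Cela1 and Dmbt1, where the ASCP tumor list has several, while Trp63 has 32 against 3 peaks and Dsg3 7 against 0.

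Genes of the epithelial to mesenchymal transition had more peaks in the ASCP tumor list by both measures. The median of the 18 genes was 0.58 by peak number (percentile 99.5) and 0.63 by covered length (percentile 99.8), with 14 members higher by number. Tgfbi, a matrix protein, had 7 peaks against 0, the repressor Zeb2 25 against 3, the collagen receptor Ddr2 22 against 4, and N-cadherin (Cdh2) 9 against 2. Gene-end peaks were in the ASCP tumor alone for 6 members and in the Pre-cancer list alone for none (percentile 99.6). With 10 kb on both sides of the genes the list median was 0.39 (percentile 97.2). The control list of genes of other tissues had the same peak-number median (0.58, percentile 99.3), but -0.0042 by covered length (percentile 78.4). The B cell list (12 genes) was, like the transition list, higher by both measures, at 0.79 (percentile 99.9) and 0.86 (percentile 99.8). Its members included Ebf1 with 42 against 3 peaks, Blk with 7 against 2 and Cd79b with 2 against 0. The recipient was immunodeficient, and peak positions do not show which cells carried these peaks.

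Other lists stood apart by 1 measure only. By covered length, tuft genes lay at 1.02 (percentile 99.5; Pou2f3, their master regulator, 21 against 5 peaks), mesothelial genes at 0.63 (percentile 98.1) and fibroblast genes at 0.37 (percentile 97.9; Fap 4 against 0, Twist2 9 against 2 peaks). Their peak-number medians were 0.38, 0.17 and 0.28, inside the central range. Endothelial genes were just inside the central range by covered length, at 0.48 (percentile 97.4; Flt1 22 against 4, Cdh5 9 against 2 peaks). For neutrophil genes, gene-end peaks were in the ASCP tumor alone for 6 of 10 (percentile 99.7), including Camp and Ly6g; the percentile was 95.9 with a window of 500 bp, 72.1 with 2500 bp and 85.2 with the widest ASCP tumor peaks. Genes of other tissues, fixed as a control, had a peak-number median of 0.58 (percentile 99.3) and a covered-length median of -0.0042 (percentile 78.4), and 7 of 20 had a gene-end peak in the ASCP tumor alone (percentile 98.2). The lists of endocrine, T cell, NK, macrophage, dendritic, pericyte, Schwann, mast cell, ductal, classical or gastric, housekeeping and proliferation genes lay inside the central range by both measures. Single ductal genes went either way: Onecut2 had 19 peaks covering 39.8 kb against 6 covering 4.02 kb, while Ehf had fewer peaks (2 against 11) but more covered length (43.0 against 9.32 kb), as did Krt7 (2 against 7 peaks, 18.9 against 4.92 kb) and Krt19 (1 against 4 peaks, 9.12 against 4.25 kb).

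Among the stem and progenitor genes, Prom1, which encodes CD133, had 42 peaks in the ASCP tumor list and 9 in the Pre-cancer list. Cd44, a hyaluronan receptor, had 20 against 6, and Dclk1, a kinase of tuft cells, 33 against 13. Aldh1a1 had 13 against 6 and was the 1 member with a gene-end peak in the Pre-cancer list alone. Lgr5 had 10 against 6, Msi1 19 against 12, Tspan8 7 against 4 and Bmi1 4 against 2 peaks. Sox9 (2 and 2) and Nes (3 and 3) had equal numbers. Relative to the median gene, 10 of the 12 members were higher and 2 lower by peak number. By covered length 5 were higher and 7 lower, the latter including Lgr5, Msi1 and Bmi1. The list of 12 did not stand apart by peak number (0.29, percentile 75.7) or by covered length (-0.21, percentile 3.71). At gene ends Aldh1a1 alone put it at percentile 2.18, a call that turned to 1 member in favour of the tumor when shallow Pre-cancer peaks were left out.

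At the loci of the mouse model, Msi2 (chromosome 11, 88339382 to 88718306) had 108 ASCP tumor peaks covering 111.6 kb and 65 Pre-cancer peaks covering 41.5 kb. Relative to the median gene its log2 ratio was 0.31 by peak number and 0.61 by covered length. Myc (chromosome 15, 61985341 to 61990361) had 2 and 1 peaks, but less covered length in the tumor list (7.77 against 9.02 kb). Relative to the median gene it lay at 0.17 and -1.01. The Gt(ROSA)26Sor locus (chromosome 6, 113067428 to 113077244), given beside them as a locus often used for transgenes, had 3 and 3 (4.90 against 5.89 kb). These are peaks of the reference loci and do not show whether an allele was recombined.

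Over all genes with at least 8 peaks, the highest ratios were those of Cd86, a costimulatory ligand of immune cells (23 against 0 peaks), Fbn1, which encodes fibrillin (20 against 0), Crim1 (35 against 1), Nrg1, an ErbB ligand (63 against 3), Tll1 (14 against 0), Oprm1 (27 against 1), Galnt18 (40 against 2), Pde1a (26 against 1), Clip4 (25 against 1) and Dmbt1 (25 against 1). The first 9 were higher by covered length too. Dmbt1, a mucin-like scavenger protein (chromosome 7, 131032057 to 131121628), was lower: 16.4 kb against 92.4 kb, since a single Pre-cancer peak spanned the gene. The lowest ratios were those of Zfp993 (0 against 13), Zfp985 (0 against 11), Ajap1 (0 against 8), Lrrtm4 (1 against 15), Cntn4 (2 against 18), Lrrn1 (1 against 11), Grm7 (2 against 16), Epha5 (1 against 10), Lingo2 (3 against 19) and Zfp982 (1 against 9). Of these 10, 9 lay on chromosomes 4 and 6, where the Pre-cancer list had more peaks of its own per Mb (21.1 and 23.7) than on most autosomes. The Zfp genes belong to a family of near-identical copies, so their peaks are uncertain.

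**Figure D3:**
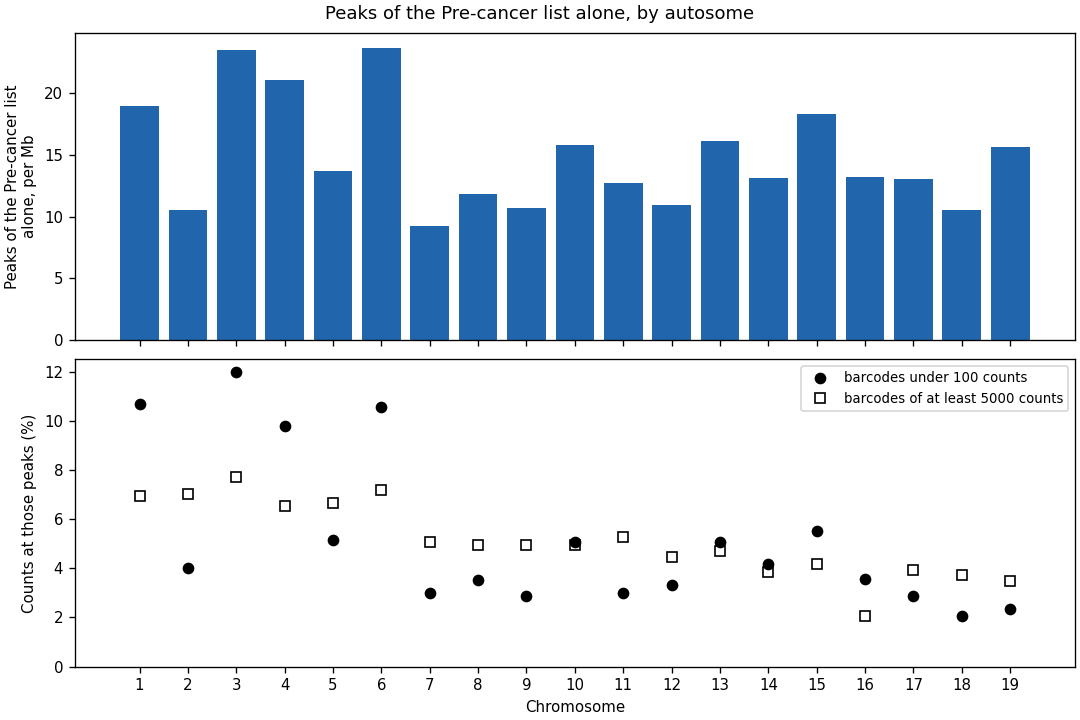
Peaks of the Pre-cancer list alone per Mb for each autosome (bars) and the percent of counts at those peaks on each autosome, in barcodes under 100 counts (filled) and of at least 5000 counts (open squares). Chromosomes 1, 3, 4 and 6 have 18.9, 23.4, 21.1 and 23.7 such peaks per Mb and 10.7%, 12.0%, 9.81% and 10.5% of the counts in shallow barcodes.

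Cells of the Pre-cancer pancreas were mostly acinar-like. Of 224 cells (median 14653 counts), 208 (92.9%, 88.7 to 95.9) were acinar-like and 16 (7.14%, 4.14 to 11.3) were ductal-like. Acinar-like names the cells left by the ductal-like rule. Of the 208, 144 had an acinar list at 0.5-fold or more of the level over all cells, a cut chosen after the result was seen. In 1 acinar-like cluster, 21 of those below it pooled to 623 CPM over the acinar list and 457 CPM over the ductal list. Both lay under the levels of the acinar-like class (3924 and 915 CPM). Of the acinar-like barcodes, 29 had under 70% of their counts in peaks shared with the tumor and a median of 1164 counts; without them the ductal-like share was 8.21% (4.76 to 13.0). The acinar list had a median of 0 CPM in these 29, a value near the floor at their depth, and they pooled to 633 CPM. The other 179 pooled to 3957 CPM with a median of 3728 CPM, and 27 of them lay below the highest ductal-like cell (717 CPM). Among these 179, 5 cells of another acinar-like cluster were picked for having at least 98% of their counts in peaks shared with the tumor. Cells of other acinar-like clusters at that share were not pooled with them. The 5 cells had 408 CPM over the acinar list and 1728 CPM over the ductal list. They were near the ductal-like class on these 2 lists but not on others. Over the squamous or basal list they had 1286 CPM against 518 CPM in that class, and over the transition list 281 CPM against 569 CPM. The small class depends on the clustering. With at least 500 counts, at least 2000 counts or resolution 0.3, no cluster met the ductal-like rule, and without a filter on peaks 34 cells did (15.2%).

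The classes are described by the genes that set them apart, which are not independent findings. The acinar list had 3924 CPM in acinar-like and 419 CPM in ductal-like cells (9.38-fold, 7.41 to 11.9), with 17 of 18 members higher; the fold was 3.62 with binarised counts and 19.1 at gene ends. Ctrb1 (chymotrypsinogen; 1362 counts), Pnlip (pancreatic lipase; 934) and Gp2 (820) had 0 counts in the ductal-like class, and the lower limits of their folds were 16.7, 11.4 and 10.0. Cela3b was 56.2-fold higher, on 2 counts in ductal-like cells (10.1 to 2226). Nr5a2 was the exception (0.84-fold, 0.60 to 1.17). Dmbt1 (47.7-fold, 18.6 to 175) also led the class, as did Pnliprp1 and Amy2b, with 0 counts in ductal-like cells and lower limits of 16.1 and 15.8. The ductal list had 1785 CPM in ductal-like and 915 CPM in acinar-like cells (1.95-fold, 1.73 to 2.20), or 2.01-fold (1.77 to 2.27) without acinar-like cells low in the acinar list. Of its 15 members, 6 were higher, including Cldn4 (10.6-fold), Spp1 (6.27-fold), Onecut2 (3.95-fold) and Glis3 (3.22-fold), and the intervals of 9 included 1, among them Krt19, Krt7 and Sox9. The class was led by Hhex, a homeobox gene of foregut and duct (26.9-fold, 14.9 to 48.7), Wnt4 (25.8-fold), Clcf1 (11.9-fold), Kcnn4 (9.24-fold) and Slc28a3 (8.91-fold).

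**Figure D4:**
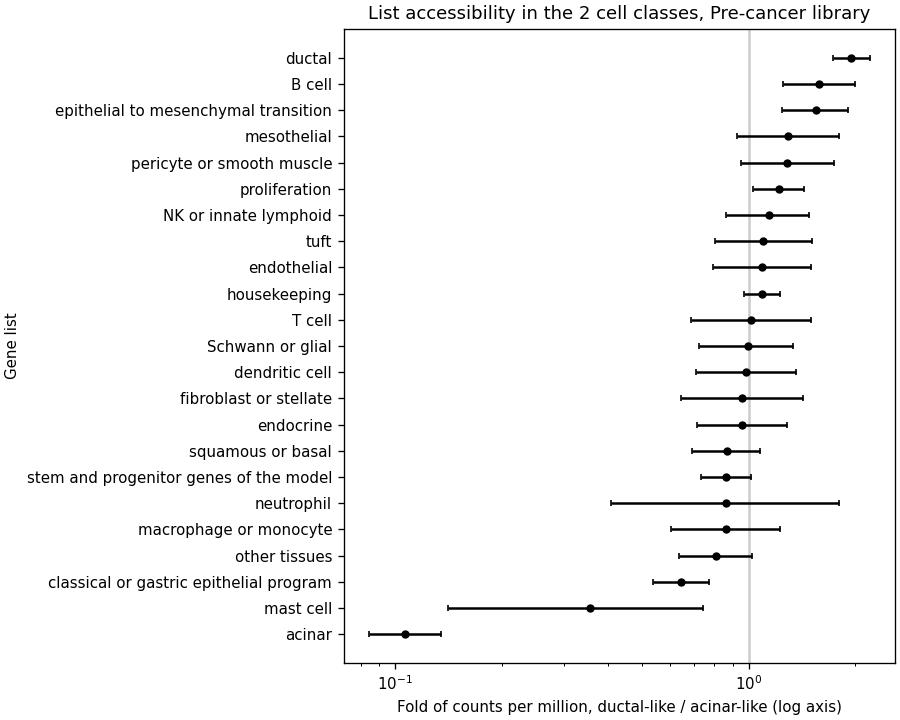
Fold of CPM in ductal-like over acinar-like cells of the Pre-cancer library for 23 gene lists, on a log axis, with 95% counting intervals. The ductal list lies at 1.95 and the acinar list at 0.11; the squamous or basal list, at 0.87, has an interval that includes 1.

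Among the other lists, the transition genes were higher in ductal-like cells (1.55-fold, 1.24 to 1.91; 6 of 18 members), as were the B cell list (1.58-fold, 1.25 to 1.998; 1 of 12 members) and the proliferation list (1.22-fold, 1.03 to 1.43; 3 of 16 members). The classical or gastric list (0.64-fold, 0.54 to 0.77; 3 of 22 members) and the mast cell list (0.36-fold, 0.14 to 0.74; 1 of 8 members, 3 with counts) were lower. The squamous or basal list did not differ detectably at this depth (0.87-fold, 0.69 to 1.07). Msi2 had 401 CPM in ductal-like and 280 CPM in acinar-like cells (1.43-fold, 1.11 to 1.85). Myc had 131 CPM against 248 CPM (0.53-fold, 0.33 to 0.80). Gt(ROSA)26Sor had 199 CPM against 238 CPM (0.84-fold, 0.58 to 1.18).

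Nearly all peaks specific to the ductal-like class were also peaks in the tumor. Of 336, 334 (99.4%, 97.9 to 99.9) overlapped the ASCP tumor list, against 93.0% (90.2 to 95.5) of matched peaks, and on average 96.8% of their length was covered, against 81.6%. Of 640 acinar-like specific peaks, 622 (97.2%, 95.6 to 98.3) overlapped, against 99.6% (99.1 to 100), and 66.7% of their length was covered, against 93.8% (92.5 to 94.9). The ductal-like peaks with most counts that overlapped lay at Csf2ra (chromosome 19, 61225268 to 61227982), at Fgfr1 and 50.5 kb from Cdkn2aipnl. The 2 that did not lay 102.2 kb from Far2 and at Eif2s3y on chromosome Y, where the ASCP tumor list had only 11 peaks in all. The acinar-like peaks with most counts that overlapped lay at Dmbt1, 1034 kb from Lrrc4c and at Cela1. The peak far from Lrrc4c held 3941 acinar-like counts in 1519 bp. No filter for regions of artificially high signal was applied here, so it may not be an accessible site. The acinar-like peaks with most counts that did not overlap lay at Amy2b (pancreatic amylase, chromosome 3, 113140441 to 113155502), Pnlip and Reg2 (a regenerating islet-derived protein). With a reciprocal overlap of 50%, the ductal-like share was 52.98%, against 57.5% (52.1 to 63.1) of matched peaks, so the excess was lost. The acinar-like share was then 52.97%, against 77.6% (74.2 to 80.6).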

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

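The test of tumor peak density, and the choice of chromosomes 1, 3, 4 and 6, were made only after the result was seen. Barcodes with under 100 counts were not used as cells, though their counts are part of the Pre-cancer totals: 114790 of them held 10.9% of the Pre-cancer counts. Of their counts at peaks of the Pre-cancer list alone, 43.1% (42.8 to 43.3) lay on chromosomes 1, 3, 4 and 6, against 28.4% (28.3 to 28.5) in barcodes with at least 5000 counts; a signal in barcodes outside the cells compared called for the closer look. Peaks of the Pre-cancer list alone were 1.69 times as dense on these chromosomes as on the other autosomes. Few tumor peaks there do not account for it, since ASCP tumor peaks per Mb stood at 0.89 of those on the other autosomes. Fragments carried over from the tumor library are argued against as well: the share differed by -0.67 percentage points in barcodes that the ASCP tumor file also lists (42.7% against 43.3%). Background DNA with more copies of these whole chromosomes remains open. In 97.0% of 67 bins of 10 Mb (65), background over cell counts at narrow peaks lay above the median bin of the other autosomes. This cannot decide, since the chromosomes were chosen after their excess in the same barcodes was seen. It shows only that the excess was not held by a few bins. Where such background DNA would come from was not tested, nor was a gain of these chromosomes in the Pre-cancer tissue.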

How the results depend on the processing

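The setting without an upper limit on counts, those on Pre-cancer peaks with at least 20 counts in barcodes of at least 5000 counts, and the one that left out cells under 2000 counts were chosen after seeing the data. No paired analysis was possible because each group has 1 library and no result comes from a test. The shared percent of Pre-cancer peaks, and of ASCP tumor peaks, was 33.7% and 19.9% with reciprocal overlap of 50%, 66.0% and 27.6% by midpoints, 82.7% and 32.8% for peaks of at least 500 bp, 59.2% and 52.4% with the widest ASCP tumor peaks cut to equal number, 89.5% and 24.9% for Pre-cancer peaks above the median count, and 89.9% and 26.2% for those with at least 20 counts in deep barcodes. Autosomes alone left both inside their intervals. Genes with a gene-end peak in 1 list alone numbered 1423 (ASCP tumor) and 594 (Pre-cancer) with the widest ASCP tumor peaks, and 98 for the Pre-cancer list with deep peaks; windows of 500 and 2500 bp kept both counts within 1.5 times. The median gene lay at 0.81 by covered length, 0.49 with pseudocount 0.5, 0.53 with 10 kb on both sides, 0.00 with the widest peaks and 0.96 by covered length of deep peaks. Under those settings the acinar list lay at -2.87, 0.25, -0.27, 0.08 and -3.01, and the squamous or basal list at 1.63, 0.25, -0.053, 0.24 and 1.96. Whether merging of neighbouring peaks caused the turn of the acinar list by covered length cannot be told from the widths, which restate it: its Pre-cancer peaks were 4.53 times as wide as all peaks by medians (1995 against 440 bp), its ASCP tumor peaks 0.89 times (509.5 against 575 bp), a test chosen after the result was seen. For the 10 kb setting the cause was not tested. The list of other tissues turned to -0.0042 and -0.15 by the 2 covered-length settings, and the stem and progenitor excess at gene ends from -1 to 1 member with deep peaks; the cause was not tested. Of 23 lists, 15 had the sign of the main value by covered length, 22 with pseudocount 0.5, 19 with 10 kb and 11 with the widest peaks.

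The ductal-like share was 0% with at least 500 counts, with at least 2000 counts and at resolution 0.3. No cluster met the rule there, and which clusters took its 16 cells was not followed. The share was 15.2% without a filter on peaks, and the cause of these changes was not tested. It was 6.15% to 7.59% with resolution 1.0, components 2 to 15, simulated doublets left out and no upper limit, each of which held all 16 cells. Results that need the class have no value where no cluster met the rule. The acinar, ductal and Msi2 folds kept direction and intervals that exclude 1 in every setting that gave one (acinar 3.62 binarised to 19.1 at gene ends, ductal 1.48 to 2.01, Msi2 1.28 to 1.97). The ductal fold of 2.01 came without acinar-like cells low in the acinar list, a setting chosen after the result was seen. The overlap of ductal-like peaks was 52.98% with reciprocal overlap of 50% and 100% of 14 peaks with at least 50 counts. That of acinar-like peaks was 95.01% at fold 2, 93.7% at fold 8, 52.97% with reciprocal overlap of 50% and 93.9% without an upper limit. The motif content of peaks was not run under any setting. Sharing was lower among Pre-cancer peaks with fewer counts (32.4% in the lowest of 10 bins), which were also narrower. The ductal-like class rests on 16 cells, which were no shallower than the acinar-like ones (medians of 18628.5 and 14021.5 counts), and 101 barcodes above 50000 counts were left out by the fixed limit.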

Other observations

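The tests of housekeeping genes and of cells low in the acinar list, and the values within shared peaks, were chosen only after the result was seen. The widest peaks, chosen after their values were seen, differed in part between the libraries. In the ASCP tumor list the widest lay 21658 bp from Ppara (52.6 kb). The next lay over Pmepa1 (50.2 kb), Mroh2a and Hjurp (48.2 kb), Frmd8 (39.6 kb), Ehf (38.7 kb), Cdh1, which encodes E-cadherin (32.0 kb), the keratin genes Krt15 and Krt19 (31.9 kb), Runx1 (31.7 kb) and Myh9 (30.6 kb). In that list 338 peaks reached 10 kb. In the Pre-cancer list 67 did, and the widest lay over Dmbt1 (92.7 kb). Peaks beside Frmd8 (28.8 kb) and over Mroh2a and Hjurp (19.3 kb) were among its widest too.

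Within the acinar-like class, the 57 cells of cluster 3 had more counts than the 61 of cluster 2, at median depths of 17089 and 13339 counts, over squamous or basal genes (1.63-fold, 1.38 to 1.93) and ductal genes (1.40-fold, 1.22 to 1.60), and also over fibroblast (1.42-fold, 1.05 to 1.95), tuft (1.33-fold, 1.02 to 1.74) and stem and progenitor genes (1.16-fold, 1.03 to 1.32), with the acinar list at 1.02-fold (0.96 to 1.09). Transition genes were lower (0.78-fold, 0.63 to 0.96), as were housekeeping genes (0.84-fold, 0.76 to 0.92). Without 9 cells of cluster 3 whose acinar list lay under 0.5-fold of the level over all cells, the squamous or basal fold was 1.44 (1.203 to 1.718), the ductal fold 1.202 (1.04 to 1.39) and the fibroblast and tuft intervals included 1. With such cells left out of cluster 2 too, the ductal interval included 1 as well (0.96 to 1.31). So did those of stem and progenitor genes (0.97 to 1.28) and transition genes (0.69 to 1.11). The squamous or basal fold was then 1.40 (1.16 to 1.69) and the housekeeping fold 0.89 (0.80 to 0.99). The ductal list had 1022 CPM in cluster 3, 731 CPM in cluster 2 and 941 CPM in the 90 cells of cluster 1. Of the 155 peaks specific to cluster 3, 98.1% overlapped the ASCP tumor list. Width and depth of the peaks do not account for this, as matched draws gave 87.1% to 95.5%. The 9 cells may carry it: without them 89.5% of 57 peaks overlapped, inside the matched draws (86.0% to 98.2%). Of the 9, 5 were picked for having at least 98% of their counts in peaks shared with the tumor. These 5 held 15.5% of the cluster's counts, with 1728 CPM over the ductal, 1286 CPM over the squamous or basal and 408 CPM over the acinar list. The peaks of the other 2 acinar-like clusters went the other way: 77.9% of 244 for cluster 1 (matched draws 85.7% to 93.0%), which holds the 29 barcodes below but had 78.9% of 218 without them (86.2% to 93.6%), and 75% of 20 for cluster 2, at the lower end of its draws (75% to 100%). Whether the clusters differ in chromatin or split by depth cannot be told apart: in held-out cells the median fold of chosen peaks was 1.27, between the bounds of 1.2 and 1.5 set beforehand, and the clusters had been made with those cells. Without the 9 cells it was 1.203. With all cells regrouped into 2 groups on odd-numbered chromosomes and read on even-numbered ones, it was 1.62. Of these 2 groups, 1 held 52 of the 57 cells of cluster 3 and the other held 56 of the 61 of cluster 2. Between them the groups also held the cells of the other clusters, so 1.62 is not a fold of cluster 3 over cluster 2. In cells simulated from 1 profile the median fold was at most 1.04.

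The 29 barcodes with at least 1000 counts and under 70% of counts in shared peaks had a median of 47.2% there, against 95.3% in the other cells. They may hold DNA without an accessible chromatin pattern: counts per kb in gene-end peaks were 0.61 of those in other peaks, against 2.43 in the other cells. These barcodes were chosen by their share in shared peaks, and within shared peaks alone the values were 1.28 and 2.21. Cells of another type cannot be told apart from this: housekeeping genes stood at 0.16 of the level in the other cells (0.051 to 0.37), but at 0.32 (0.10 to 0.74) per count in shared peaks, an interval that includes 0.5. No other biological explanation was tested. At Pre-cancer-only peaks, 28.4% of their counts (27.8 to 29.0) lay on chromosomes 1, 3, 4 and 6.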
